A study of Mus musculus with 6 samples.

How the data were processed

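RNA was measured in 6 liver libraries from male C57BL/6 mice, 3 control and 3 model. C57BL/6 is a common inbred laboratory strain. Groups and replicate numbers were taken from the sample titles. The series text speaks of triplicate liver samples per group, and the labels do not say whether each library came from 1 mouse, nor give a litter, cage, batch or sequencing date, so the p-values measure the spread between these 6 libraries.

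Per the labels' protocols, total RNA was extracted with Trizol, checked on a Bioanalyzer and sequenced on an Illumina NovaSeq instrument. HISAT2, a read aligner, and the mouse genome build GRCm39 are named in the submitters' processing notes without a version. The tool that counted reads, its strand setting, the gene annotation release and any read filter are not given in the sources used here. Per the file headers, the deposited table holds a read count per gene for each of the 6 libraries, and these counts are whole numbers that were not normalized. Per the file headers it also holds the authors' FPKM values, gene lengths and gene positions. The FPKM values the authors deposited equal the count divided by gene length and by the total count of the column, so they carry no correction for composition. Positions are given as in the table, on GRCm39.

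The table has 21898 genes, of which 3673 had no count in any library, and no row without a gene. Symbols were used as the table gives them, and 21794 of its gene identifiers were found in the GENCODE names available for comparison. A symbol was carried by more than 1 row in 20 cases, covering 42 rows. For a list member with such a symbol, the row with most counts was used. Total counts ran from 11766047 to 15109508 per library. A floor of 3 counts in a library corresponds to 0.199 to 0.255 CPM, counts scaled to a common library size. Floors and counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

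Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10), which left 12656 genes and removed 9242. Library sizes were scaled with TMM factors, which were 0.81, 0.84 and 0.89 in the control and 1.19, 1.21 and 1.15 in the model libraries. The model held the group alone. Robust quasi-likelihood fits and F tests were used, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A second count required a change of at least 2-fold. Standard errors (SE) of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled with TMM and given as mean ± SD over 3 libraries. Every log2 fold change is model over control.

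Before the data were examined, 39 gene lists were fixed: pathways of lipid, sterol, glucose, bile acid, drug and amino acid metabolism, stress and immune responses, sex-biased liver genes, markers of liver and other cell types, and lists for sample quality. They held 747 distinct genes, of which 736 were in the table and 685 were tested. Some lists share members, so they are not independent. Slco1a1 and Cyp7b1 stand in the bile acid and male-biased lists, and Cyp2a4 and Cyp2b9 in the drug and female-biased lists. Lists with at least 5 tested members were tested with camera of limma 3.58.1, with its preset correlation between genes of 0.01, and adjusted over the 37 lists tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. The members past the threshold were counted over all genes tested and again adjusted over the list alone.

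The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 5 largest rises and the 5 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 2 members with the smallest p of each main list, and the member with the smallest p of each other list if past the threshold. Among the rises, 1 gene known only by a model identifier was passed over. Further list members, and the gene families and annotation terms of the closing section, were chosen as examples after their values were seen.

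The scripts were run on simulated counts first, with 200 genes changed by known factors in the comparison of model with control and 11478 genes tested. The fits recovered 91.7% of genes changed 4-fold, 46.2% of those changed 2-fold and 8.62% of those changed 1.5-fold. Over 20 simulations a mean of 9.24% of the calls were unchanged genes, with a highest value of 15.5%, against a nominal 5%. With no gene changed, the median was 1 call and the highest 5 calls. Of the lists 2 of 2 changed by 1.5-fold were called, and 0 of 33 unchanged ones. The simulated genes varied independently, so correlation between genes is not covered. Far fewer genes were changed than were called in the real comparison, and no shift in composition was simulated. These rates need not hold for the real data. In mixed splits of the 6 libraries camera with its preset correlation called 7 to 24 lists. Such splits put 2 libraries of 1 group with 1 of the other and keep part of the real difference. These counts are therefore not false-call rates.

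The alternatives tried were RLE, upper-quartile and no scaling factors, no filter and a filter at a mean of 5 CPM, a replicate block, fits without robust dispersion, leaving out each library, DESeq2 1.42.0, limma-voom, glmTreat against a 1.5-fold change, leaving out 91 genes of multigene families, library sizes without the 20 genes with most counts, and the other list tests. Limma-trend on log2(FPKM + 1), for genes with a mean FPKM of at least 1, and a fit without the library with most mitochondrial counts of each group were added after seeing the data. Members of near-identical families (Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gsta, Mup, Serpina1 and Serpina3 genes) are uncertain, because the counting of reads that match several copies is not stated. The spans of Dmbt1, Hsd3b5, Acss2, Mvd, Abcg5, Prodh, Cebpb, Cxcl10, Mmp12, Col4a1, Alas2, Glul, Elovl3, Irf7, Ccnd1, Dbp, Cideb, Abcg8, Cebpd, Sod1, Ppp1r15a and Stab1 overlap a gene on the other strand, so reads in the overlap may belong to either gene.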

Results

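Liver RNA of male mice was sequenced in 6 libraries, 3 from control mice and 3 from a mouse model of type 2 diabetes with steatotic liver disease. Control mice ate chow and received citrate buffer. Model mice were kept for 8 weeks on a diet with 60% of fat and 20% each of protein and carbohydrate, followed by streptozotocin, a toxin of the insulin-producing beta cells, at 60 mg/kg on 3 days. A fasting glucose between 15 and 25 mmol/L defined the diabetic state, and livers were taken 6 weeks after that measurement. Diet and toxin were always given together, so the comparison is between the combined regimens. Libraries held 12624162 ± 744136 counts in the control group and 14917013 ± 205520 counts in the model group (mean ± SD, n = 3 each).

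The comparison of model with control livers asked which liver transcripts differ in this disease model. All 25 tested genes of cholesterol synthesis and 14 of 21 genes of fatty acid synthesis were lower in the model livers. Genes of the lipid-associated macrophage list, which also holds general myeloid genes (18 of 19), interferon-response genes (22 of 26), p53 targets (16 of 18) and cell cycle genes (19 of 22) were higher. Mvd, a decarboxylase of the mevalonate pathway, was 14.7-fold lower, at 73.8 ± 10 CPM in control and 5.03 ± 1.49 CPM in model livers (n = 3 each). Trem2, a receptor of lipid-associated macrophages, was 24.1-fold higher, at 0.574 ± 0.242 against 13.8 ± 2.50 CPM. Alb, which encodes serum albumin, was 4.94-fold lower and took 7.02% ± 0.769 of all counts in control but 1.98% ± 0.267 in model libraries.

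Of 12656 genes tested, 4388 (34.7%) passed the edgeR threshold, 2650 higher and 1738 lower in the model. Of these, 2079 were higher and 604 lower by at least 2-fold. The groups did not overlap for 6406 genes (50.6%), where chance gives 10%. The first principal component held 77.2% of the variance and separated the groups. The balance of higher and lower calls depended on the scaling. With TMM factors 60.4% of the calls were higher, with upper-quartile factors 69.6%, and with total counts alone 91.7% (5568 higher and 507 lower). Using total counts moved the median of all genes by 0.48 on the log2 scale and upper-quartile factors moved it by 0.10, so changes here are relative to the median gene.

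**Figure D1:**
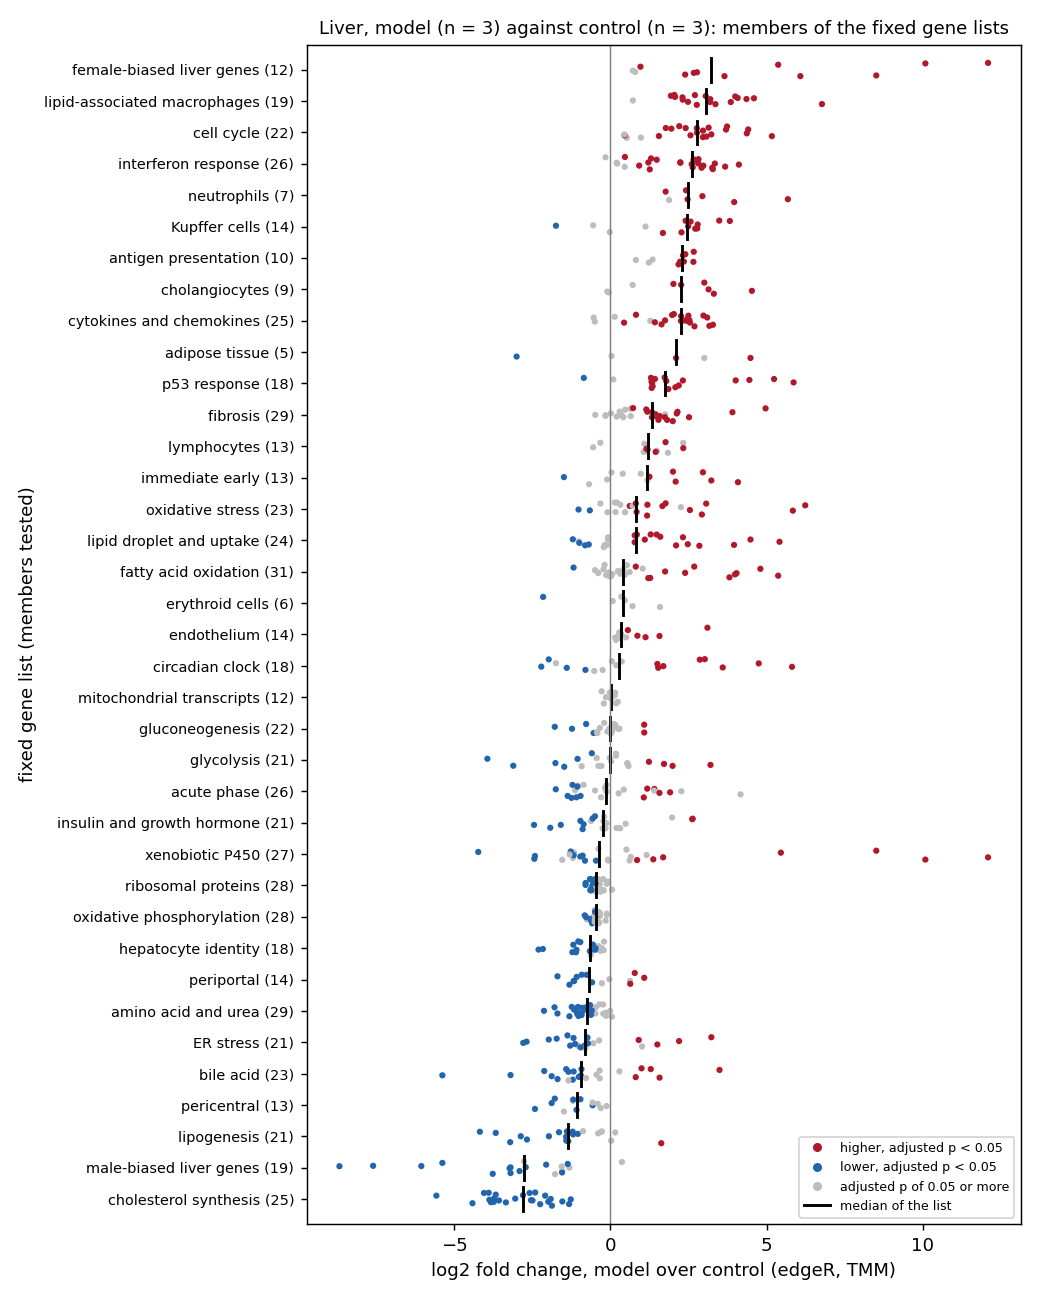
Log2 fold change (x axis, model over control, edgeR with TMM, 3 libraries per group) of each tested member of 37 fixed gene lists (y axis, members tested in brackets). Red and blue points passed an adjusted p of 0.05 and grey points did not, and black bars are list medians, from -2.80 for cholesterol synthesis to 3.21 for female-biased liver genes. The medians of oxidative phosphorylation and ribosomal proteins (both -0.47) become 0.02 under scaling by total counts, and those of gluconeogenesis, glycolysis, acute phase, insulin and growth hormone, and xenobiotic P450 also change sign.

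Among the genes chosen by the rule, Hsd3b5 had the largest fall. Hsd3b5, a male-specific hydroxysteroid dehydrogenase (ENSMUSG00000038092, chromosome 3, 98525950 to 98537568, GRCm39), was 409-fold lower (log2 fold change -8.68, SE 0.38, adjusted p = 2.3e-06, edgeR). It had 350.0 ± 37.2 CPM in control and 0.839 ± 0.542 CPM in model livers, with a log2 fold change of -9.29 without model replicate 2. Serpina1e, an alpha-1-antitrypsin paralog (chromosome 12, 103913190 to 103925234), had a log2 fold change of -7.60 (SE 1.28), and the major urinary protein genes Mup15 and Mup16 had -6.20 (SE 1.31) and -6.14 (SE 1.24). With 1 library left out, the log2 fold change of Serpina1e lay between -9.56 (without model replicate 2) and -7.14 (without model replicate 1), and its call ended without both control replicate 1 and model replicate 3 (adjusted p = 0.107). Without model replicate 1 the calls of Mup15 and Mup16 ended, with adjusted p = 0.0711 and 0.0643. Without model replicate 2 their log2 fold changes were -7.17 and -7.04, and Mup16 had -5.13 without control replicate 1. Moxd1, a monooxygenase-like gene, had -7.36 (SE 1.95, adjusted p = 0.0388), but its control libraries ran from 0.858 to 75.0 CPM. Its call ended without any of control replicates 1 and 2 or model replicates 1, 2 and 3 (adjusted p from 0.0820 to 0.146), and its log2 fold change lay between -8.54 (without model replicate 2) and -6.26 (without control replicate 1).

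Cyp2a4 (chromosome 7, 26006594 to 26014513) and Cyp2b9 (chromosome 7, 25872836 to 25910086), cytochrome P450 genes of the female liver, showed the largest rises. Cyp2a4 rose by 12.09 on the log2 scale (SE 0.88), from 6 counts over the control libraries to 44723 over the model libraries. Its near-identical neighbour Cyp2a5, chosen after its values were seen, was also higher (1.69, SE 0.38), so the split of reads between them is uncertain. Cyp2b9 rose from 0.242 ± 0.259 to 93.8 ± 28.5 CPM (log2 fold change 8.51, SE 0.48), and its log2 fold change was 9.77 without control replicate 3, since the control libraries held 8 counts. Ly6d, a lymphocyte antigen family member, rose from 0.966 ± 0.279 to 278 ± 192 CPM (8.15, SE 0.64, or 7.42 without model replicate 3). Psrc1, a microtubule-associated gene, had 2 counts over the control and 864 over the model libraries, a ratio of 262 with a 95% exact counting interval of 72.3 to 2168. Dmbt1, a scavenger receptor gene, had 2 against 920 counts, a ratio of 279 (77.0 to 2308). The 2 control counts lay in control replicate 2, so that library sets the ratio. The call of Dmbt1 ended without control replicate 1, 2 or 3 (adjusted p = 0.0720, 0.119 and 0.0591).

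Genes of cholesterol synthesis fell as a group. All 25 tested members were lower, over all genes and adjusted over the list alone, with a median log2 fold change of -2.80, or -2.31 under total counts (camera adjusted p = 5.92e-37; adjusted p = 0.0926 with an estimated correlation). Mvd fell by 3.88 (SE 0.23, adjusted p = 8.1e-06) and Nsdhl, a sterol dehydrogenase, by 3.57 (SE 0.22). Sqle, the squalene epoxidase, fell by 3.83 (SE 0.30). For fatty acid synthesis 14 of 21 genes were lower and 1 was higher, or 15 and 1 adjusted over the list alone (median -1.35, or -0.87 under total counts; camera adjusted p = 2.83e-08; adjusted p = 0.163 with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, fell by 3.67 (SE 0.34), Acly by 1.97 (SE 0.34), the fatty acid synthase gene Fasn by 3.21 (SE 0.45) and the desaturase gene Scd1 by 2.67 (SE 0.52). Fasn had -3.94 without model replicate 1. The calls of Fasn and Scd1 ended without both control replicate 1 and model replicate 3 (adjusted p = 0.0900 and 0.0861). The member that rose was Scd2, a desaturase paralog, at 7.44 ± 0.458 against 23.0 ± 3.74 CPM (1.63, SE 0.18).

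Genes of fatty acid oxidation and of lipid storage moved in part. For oxidation and related PPAR-alpha targets 11 of 31 genes were higher and 1 lower, or 13 and 1 adjusted over the list alone (median 0.41; camera adjusted p = 2.5e-04; adjusted p = 0.342 with an estimated correlation). Vnn1, a pantetheinase, rose from 20.2 ± 0.388 to 129.5 ± 22.1 CPM (2.68, SE 0.17), and Cyp4a31, a fatty acid omega-hydroxylase gene, rose by 3.99 (SE 0.27). The peroxisomal Ehhadh rose by 1.75 (SE 0.19) and Cpt1a, the gate of mitochondrial fatty acid import, by 1.27 (SE 0.22). Pdk4 was the member that fell, a call that ended without control replicate 1, 2 or 3 or model replicate 1 (adjusted p from 0.0901 to 0.104). For lipid droplets and uptake 14 of 24 genes were higher and 4 lower, or 14 and 5 adjusted over the list alone (median 0.81; camera adjusted p = 0.0030; adjusted p = 0.152 with an estimated correlation). Cidec, a lipid droplet protein, rose from 2.14 ± 0.374 to 47.8 ± 15.2 CPM (4.48, SE 0.28). The fatty acid transporter Cd36 rose by 2.85 (SE 0.23) and lipoprotein lipase, Lpl, by 2.47 (SE 0.34). The 4 that fell were Plin5, Abhd5, Fabp1 and Cideb, the last not called without control replicate 2 or 3 or model replicate 1 or 3 (adjusted p from 0.0585 to 0.137). Under total counts Abhd5 had -0.21 (adjusted p = 0.262), Fabp1 -0.71 (0.0638) and Cideb -0.33 (0.359), none of them called.

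The 3 lists of glucose metabolism and its hormones did not pass with camera, though 2 of them passed in some alternatives. For gluconeogenesis 2 of 22 genes were higher and 4 lower, or 2 and 3 adjusted over the list alone (median -0.02, which becomes 0.47 under scaling by total counts; camera adjusted p = 0.267). Pck1, the cytosolic phosphoenolpyruvate carboxykinase, rose by 1.08 (SE 0.23) and its mitochondrial paralog Pck2 by 1.08 (SE 0.23). Tat, tyrosine aminotransferase, fell by 1.23 (SE 0.21), and Glul, G6pc and Gcgr also fell. The call of Gcgr ended without control replicate 1 or 3 or model replicate 1, 2 or 3 (adjusted p from 0.0563 to 0.112). Under total counts G6pc had -0.29 (adjusted p = 0.242) and Gcgr -0.05 (0.848), neither called. For glycolysis and glycogen 4 of 21 genes were higher and 6 lower, with the same counts adjusted over the list alone (median -0.02, or 0.46 under total counts; camera adjusted p = 0.175). Pkm, the pyruvate kinase of other cell types, rose by 1.99 (SE 0.17), and the hexokinase genes Hk1 and Hk2 and the kinase gene Pfkfb3 rose too. For insulin and growth hormone signalling 2 of 21 genes were higher and 8 lower, both also adjusted over the list alone (median -0.23, or 0.28 under total counts; camera adjusted p = 0.0888). Trib3 rose by 2.63 (SE 0.30) and Cish rose as well. Glycolysis passed without model replicate 1 (camera adjusted p = 0.0185) and with no filter on low counts (0.0496). Insulin and growth hormone signalling passed without control replicate 3 (0.0417), with no filter (0.0207) and by fry (0.0189). The growth hormone receptor gene Ghr fell by 1.93 (SE 0.27) and Egfr by 2.45 (SE 0.30).

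**Figure D2:**
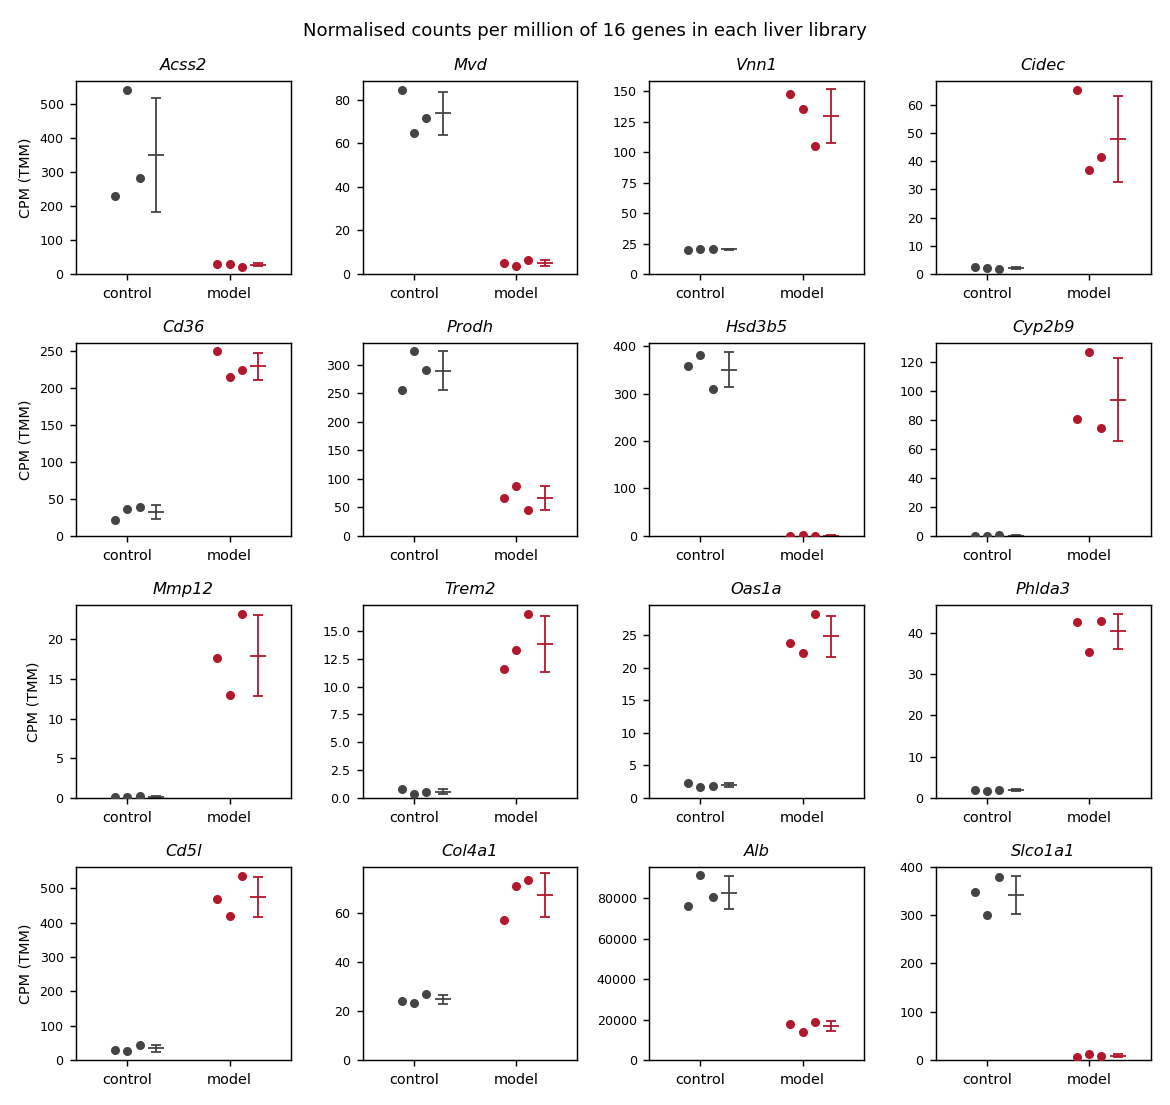
CPM scaled with TMM (y axis, from 0) in each of 3 control and 3 model livers (x axis) for a selection of genes, with 1 point per library and, beside the points, the mean ± SD. In each panel the groups do not overlap, as for Slco1a1 (342 against 8.19 CPM) and Cd36 (31.8 against 229 CPM).

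Hepatocyte functions other than lipid synthesis were lower in part. For amino acid breakdown and the urea cycle 20 of 29 genes were lower and 0 higher, or 21 lower adjusted over the list alone (median -0.77, or -0.28 under total counts; camera adjusted p = 8.63e-08; adjusted p = 0.20 with an estimated correlation). Prodh, proline dehydrogenase, fell by 2.13 (SE 0.24), Haao, of tryptophan breakdown, by 1.79 (SE 0.20) and Cps1, the entry enzyme of the urea cycle, by 1.70 (SE 0.26). For bile acid synthesis and transport 12 of 23 genes were lower and 5 higher, with the same counts adjusted over the list alone (median -0.95, or -0.46 under total counts; camera adjusted p = 7.76e-04; adjusted p = 0.331 with an estimated correlation). The anion transporter Slco1a1 fell from 342 ± 39.5 to 8.19 ± 2.98 CPM (-5.38, SE 0.28), and Cyp7b1 and the bile salt export pump Abcb11 fell by 3.20 (SE 0.58) and 1.42 (SE 0.22), with -3.95 for Cyp7b1 without model replicate 2. The 5 that rose were the exporter genes Abcg5 (1.57, SE 0.18), Abcg8, Abcb4, Abcc3 and Abcc4, of which Abcc3 was not called without control replicate 1 or 2 or model replicate 1 or 2 (adjusted p from 0.0629 to 0.0725). For drug-metabolising P450 genes and their regulators 7 of 27 were higher and 9 lower, or 7 and 11 adjusted over the list alone. The median (-0.38, or 0.09 under total counts) and the mean (0.84) differed in sign, and camera gave an upward direction with an adjusted p = 0.785. Cyp2a22 rose by 5.45 (SE 0.33), and Cyp2c29 fell by 4.23 (SE 0.45).

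Markers of hepatocytes were lower too. Of 18 hepatocyte identity genes 12 were lower and 0 higher, also adjusted over the list alone (median -0.64, or -0.16 under total counts; camera adjusted p = 1.7e-05; adjusted p = 0.0926 with an estimated correlation). Alb fell by 2.30 (SE 0.24) and Apoa1, the main HDL protein, by 1.10 (SE 0.23). Of 13 pericentral genes 7 were lower and 0 higher on both adjustments, adjusted over the list alone included (median -1.09, or -0.60 under total counts; camera adjusted p = 1.1e-04; adjusted p = 0.331 with an estimated correlation), with Cyp1a2 down by a log2 fold change of -2.42 (SE 0.27). Of 14 periportal genes 8 were lower and 3 higher, Pck1 and Ctsc among the latter, or 8 and 4 adjusted over the list alone (median -0.68, or -0.20 under total counts; camera adjusted p = 0.0199; adjusted p = 0.373 with an estimated correlation). Cyp2f2 fell by 1.18 (SE 0.17). Ctsc was not called without control replicate 1 or 3 or model replicate 1 or 3 (adjusted p from 0.0526 to 0.131). The periportal call ended without control replicate 2 (camera adjusted p = 0.0723) and without model replicate 1 (0.0627).

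Sex-biased liver genes moved in opposite directions. Of 19 male-biased genes 13 were lower and 0 higher, or 16 lower adjusted over the list alone (median -2.77, or -2.25 under total counts; camera adjusted p = 9.41e-18; adjusted p = 0.152 with an estimated correlation). Beside Hsd3b5, the fatty acid elongase gene Elovl3 fell by 6.06 (SE 0.82), with a log2 fold change of -6.77 without model replicate 2. Of 12 female-biased genes 10 were higher and 0 lower, also adjusted over the list alone (median 3.21; camera adjusted p = 1.02e-10; adjusted p = 0.0926 with an estimated correlation). Of the 20 listed genes 8 had too few counts to be tested, and members nearly silent in the control livers could be tested only if they rose. With no filter 14 of 20 were higher and 0 lower (median 3.03). Cyp2b9 had the smallest p of this list. All mice were male per the series description, and the Y-linked genes Ddx3y, Uty and Eif2s3y had between 96 and 1230 counts in every library. Kdm5d, the other Y-linked gene tested, had a log2 fold change of -0.56 (SE 0.19, adjusted p = 0.0379), which moved to -0.08 with adjusted p = 0.764 under total counts, and its call ended without control replicate 1, 2 or 3 or model replicate 1 or 3 (adjusted p from 0.0632 to 0.127).

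Inflammatory and macrophage genes were higher. Of 19 tested genes of the lipid-associated macrophage list 18 were higher and 0 lower, also adjusted over the list alone (median 3.05; camera adjusted p = 4.57e-18; adjusted p = 0.152 with an estimated correlation). The list also holds monocyte and general myeloid genes, such as Ccr2, Ly6c2, Itgam, Lyz2 and Cd68. Its count therefore does not single out lipid-associated macrophages. Mmp12, a macrophage elastase, rose from 0.151 ± 0.0920 to 17.9 ± 5.12 CPM (6.77, SE 0.41, or 7.39 without control replicate 3), Trem2 rose by 4.59 (SE 0.32), Gpnmb by 4.07 (SE 0.31) and Spp1, osteopontin, by 2.31 (SE 0.25). Of 25 cytokine and chemokine genes with their receptors and regulators 21 were higher and 0 lower, or 22 and 1 adjusted over the list alone (median 2.26; camera adjusted p = 3.93e-09; adjusted p = 0.152 with an estimated correlation). Cxcl10 rose by 3.28 (SE 0.30), Tlr2 by 2.49 (SE 0.26) and Tnf by 2.47 (SE 0.46), the last from 0.353 ± 0.150 to 1.95 ± 0.149 CPM. Of 26 interferon-response genes 22 were higher and 0 lower, or 23 adjusted over the list alone (median 2.61; camera adjusted p = 3.28e-22; adjusted p = 0.152 with an estimated correlation). Oas1a rose by 3.67 (SE 0.21) and Irf7 by 2.70 (SE 0.23).

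Most tested markers of Kupffer cells, antigen presentation and neutrophils were higher too. Of 14 Kupffer cell markers 10 were higher and 1, Cd163, was lower, also adjusted over the list alone (median 2.45; camera adjusted p = 8.47e-11; adjusted p = 0.152 with an estimated correlation). Cd5l rose from 33.6 ± 9.66 to 475 ± 58.4 CPM (3.82, SE 0.24) and Clec4f by 2.56 (SE 0.22). For antigen presentation 7 of 10 genes were higher, or 9 adjusted over the list alone (median 2.27; camera adjusted p = 3.58e-09; adjusted p = 0.152 with an estimated correlation), among them the MHC class II genes H2-Eb1 (2.23, SE 0.18) and Cd74 (2.32, SE 0.19). Of 7 neutrophil genes 6 were higher, or 7 adjusted over the list alone (median 2.47; camera adjusted p = 5.3e-04; adjusted p = 0.305 with an estimated correlation), Csf3r by 2.42 (SE 0.31). Only 7 of 12 listed neutrophil genes and 13 of 18 lymphocyte genes were tested. Members nearly silent in the control livers could be tested only if they rose, which favours rises in these lists. Of 13 lymphocyte genes 5 were higher (Jchain, Cd3d, Nkg7, Gzmb and Ms4a1), or 6 adjusted over the list alone, and the list did not pass (median 1.19; camera adjusted p = 0.0889). It passed without model replicate 1 (0.0399) and by fry (0.0184). Without 1 library the calls of Cd3d, Nkg7, Gzmb and Ms4a1 ended, at highest with adjusted p = 0.0955 (control replicate 2), 0.107 (control replicate 3), 0.117 (model replicate 3) and 0.157 (model replicate 2). Jchain, the joining chain of antibodies, had a log2 fold change of 1.19 (SE 0.28).

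Acute-phase genes went both ways. Of 26 genes 5 were higher (Cebpb, Cebpd, Socs3, Serpina3n and Orm3) and 7 lower, or 6 and 8 adjusted over the list alone. The median was -0.16 (0.33 under total counts), the mean 0.10, and camera gave a downward direction with adjusted p = 0.476. The transcription factor Cebpb rose by 1.41 (SE 0.21), while Crp, C-reactive protein, fell by 1.37 (SE 0.23) and the fibrinogen chain Fgg by 1.21 (SE 0.24). Orm3 was not called without control replicate 2 (adjusted p = 0.0546).

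Genes of matrix, bile ducts and vessels were higher in part. Of 29 fibrosis genes 17 were higher and 0 lower, or 20 adjusted over the list alone (median 1.33; camera adjusted p = 5.34e-06; adjusted p = 0.305 with an estimated correlation). Tgfb1, a fibrogenic cytokine, rose from 6.49 ± 1.02 to 22.8 ± 1.40 CPM (1.81, SE 0.18), Col4a1 by 1.45 (SE 0.15) and Col1a1 by 2.15 (SE 0.33). Of 9 cholangiocyte markers 6 were higher, or 7 adjusted over the list alone (median 2.26; camera adjusted p = 8.32e-06; adjusted p = 0.0926 with an estimated correlation), with Epcam at 2.02 (SE 0.20) and Krt19 at 3.00 (SE 0.31). Only 9 of 11 listed cholangiocyte genes had enough counts to be tested. Of 14 endothelial markers 5 were higher (Lyve1, Cdh5, Pecam1, Oit3 and Stab1), also adjusted over the list alone. The endothelial median was 0.33 (camera adjusted p = 0.0030; adjusted p = 0.305 with an estimated correlation), and Lyve1 rose by 3.10 (SE 0.25). Stab1 was not called without control replicate 2 or 3 or model replicate 2 or 3 (adjusted p from 0.0618 to 0.0896).

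Stress and growth genes changed as well. Of 18 p53 targets 16 were higher and 1, Bbc3, was lower, also adjusted over the list alone (median 1.76; camera adjusted p = 6.19e-15; adjusted p = 0.0926 with an estimated correlation). Phlda3 rose from 1.84 ± 0.245 to 40.3 ± 4.24 CPM (4.45, SE 0.19) and the cell cycle inhibitor Cdkn1a by 4.01 (SE 0.42). Of 22 cell cycle genes 19 were higher, or 20 adjusted over the list alone (median 2.77; camera adjusted p = 3.05e-08; adjusted p = 0.223 with an estimated correlation), with Mcm6, of the replicative helicase, at 2.20 (SE 0.23) and Ccnd1, cyclin D1, at 2.96 (SE 0.38), or 3.65 without control replicate 3. Of 23 oxidative stress genes 12 were higher and 2, Sod1 and Cat, lower, or 15 and 2 adjusted over the list alone (median 0.81; camera adjusted p = 5.5e-04; adjusted p = 0.365 with an estimated correlation). Hmox1, heme oxygenase, rose by 3.06 (SE 0.29) and Nqo1 by 2.93 (SE 0.39). Of 21 genes of endoplasmic reticulum stress 12 were lower and 4 higher, or 13 and 4 adjusted over the list alone (median -0.83, or -0.34 under total counts; camera adjusted p = 0.0015; adjusted p = 0.393 with an estimated correlation). Those lower included the chaperones Hspa5 (-1.72, SE 0.28) and Calr (-1.18, SE 0.19) and the 4 higher were Sesn2 (2.20, SE 0.22), Atf3, Ppp1r15a and Chac1. Of 13 immediate early genes 6 were higher and 1, Hspa1b, lower, or 8 and 1 adjusted over the list alone (median 1.18; camera adjusted p = 0.0084; adjusted p = 0.331 with an estimated correlation), Jun by 2.09 (SE 0.21). That call ended without control replicate 2 (camera adjusted p = 0.0580). Leaving out 1 library also ended the calls of Bbc3 (adjusted p = 0.0645 without model replicate 1, 0.0602 without model replicate 2) and Hspa1b (0.0708 without control replicate 1, 0.0606 without control replicate 3). It ended those of Ppp1r15a (up to 0.0844, control replicates 2 and 3 and model replicate 1) and Chac1 (up to 0.0678, control replicates 2 and 3 and model replicate 2). The call of Cat ended without any 1 of the 6 libraries (0.0548 to 0.12).

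Of 18 circadian clock genes 8 were higher and 4 (Nfil3, Clock, Cry1 and Arntl) lower, also adjusted over the list alone, and the list did not pass (median 0.27; camera adjusted p = 0.267). It passed in some alternatives, 1 of them without model replicate 3 (0.0386). Camera asks for a shift in one direction, so opposite moves within this list cancel. Fry asking for moves in either direction gave an adjusted p = 0.0048. By the same test gluconeogenesis had 4.1e-04 and acute phase 2.7e-04, lists that did not pass camera either. Every list tested except mitochondrial transcripts (0.805) passed this form of fry, erythroid genes included (0.0287). A pass therefore does not set these lists apart from the others. Arntl was not called without control replicate 1, 2 or 3 or model replicate 2 (adjusted p from 0.0531 to 0.0815). Per1 rose by 2.86 (SE 0.26) and the clock output gene Dbp by 5.81 (SE 0.85), or 6.48 without control replicate 2. Time of day and feeding state at liver collection were not among the sample details used here, so a difference in either between the groups could not be checked. Among 28 genes of oxidative phosphorylation 7 were lower and 0 higher, also adjusted over the list alone, with a median of -0.47 that becomes 0.02 under total counts (camera adjusted p = 7.46e-04; adjusted p = 0.238 with an estimated correlation). Cox5a had -0.63 (SE 0.15), or -0.15 with adjusted p = 0.503 under total counts. Of 28 ribosomal protein genes 14 were lower and 0 higher, or 18 adjusted over the list alone, again with a median of -0.47 that becomes 0.02 under total counts (camera adjusted p = 4.5e-04; adjusted p = 0.331 with an estimated correlation). Rps2 had -0.80 (SE 0.16), or -0.31 with adjusted p = 0.146 under total counts.

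Lists for other tissues and for sample quality were measured alongside. Mitochondrially encoded transcripts took 13.1%, 8.25% and 8.12% of counts in the control libraries and 10.99%, 13.8% and 19.1% in the model libraries, and 0 of 12 such genes passed (edgeR, 0 also at an unadjusted p under 0.05; median 0.02; camera adjusted p = 0.745). Of 6 erythroid genes 1, Alas2, was lower and none was adjusted over the list alone (median 0.40, while the camera adjusted p was 0.969). Alas2, of heme synthesis, had -2.16 (SE 0.60, adjusted p = 0.0363), and its call ended under total counts (adjusted p = 0.0696) and without control replicate 1, 2 or 3 or model replicate 1 (0.0684 to 0.108). Of 5 adipose genes Cidec and Fabp4 were higher and Car3 lower, also adjusted over the list alone (median 2.10; camera adjusted p = 0.0446; adjusted p = 0.223 with an estimated correlation). Only these 5 of 10 listed adipose genes had enough counts to be tested. The adipose call ended without control replicate 1, 2 or 3 or model replicate 2 (camera adjusted p = 0.0567, 0.0723, 0.0593 and 0.291). Of 15 genes of the pancreas 1 was abundant enough to be tested and did not differ detectably (log2 fold change 0.04).

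Across the 37 lists tested, camera with its preset correlation called 28, 17 higher and 11 lower, fry called 29, and camera with an estimated correlation called 0, with 12 at an unadjusted p under 0.05. The counts of members rest on the gene-wise edgeR tests, but members of a list can move together. The estimated correlation was 0.43 for cholesterol synthesis and 0.59 for lipid-associated macrophages. A count of members is therefore not a count of independent results. Model libraries had at least 1 count for 16592 ± 269 genes and control libraries for 14022 ± 96.4 (SD, n = 3). Thinned to the shallowest total of 11766047 counts, the model libraries had 16085 to 16579 and the control libraries 13916 to 14040.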

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

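The tests on FPKM and without control replicate 1 and model replicate 3, the libraries with most mitochondrial counts of their groups, were chosen only after the result was seen. The count of 4388 genes stayed between 3395 and 4867 under RLE and upper-quartile factors, no filter, fits without robust dispersion, DESeq2, limma-voom, leaving out each library, the multigene families, the top 20 genes or those 2 libraries (4311). The count of 28 lists stayed between 24 and 29 in the list tests other than camera with an estimated correlation, but the lists called differed. Fry ended the call of endoplasmic reticulum stress (adjusted p = 0.0675) and added insulin and growth hormone (0.0189) and lymphocytes (0.0184). The 5 CPM filter ended periportal (0.0732) and immediate early (0.0903), and left 34 lists to test, without neutrophils, adipose and lymphocytes. Total counts ended adipose (0.129). No filter ended adipose (0.0993) and added glycolysis (0.0496) and insulin and growth hormone (0.0207). Leaving out 1 library ended or added the calls given in the report. No call shared with these or the alternatives below changed sign.

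Scaling by total counts gave 5568 higher and 507 lower genes, since it removes the factors that set the median gene near 0. A filter at a mean of 5 CPM left 9411 genes and gave 2731 calls, 1604 higher and 1127 lower, 1380 of them at least 2-fold. Testing against a 1.5-fold change with glmTreat, a stricter null by construction, gave 2254 calls, 1736 higher and 518 lower. FPKM with limma-trend, which carries no composition factors and tested 9455 genes, gave 4062 calls with 454 lower and 1304 at least 2-fold. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower. The estimate was 0.43 for cholesterol synthesis and 0.59 for lipid-associated macrophages, so their small camera p-values rest in part on the preset 0.01. It was -0.0022 for hepatocyte identity and -0.024 for lipid droplets and uptake, which were not called either (adjusted p = 0.0926 and 0.152). A higher correlation cannot account for these lists. Camera with an estimated correlation also uses the few residual degrees of freedom of the 6 libraries, which by itself raises p-values. The loss of all calls is therefore not a measure of correlation alone.

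The lists that changed direction were never called in the settings named here. Under total counts the adjusted p was 0.628 for xenobiotic P450 and 0.532 for erythroid genes. Erythroid genes had 0.931 under upper-quartile factors and 0.958 under the 5 CPM filter, and the mitochondrial list had 0.961 by fry. Without the 2 libraries both xenobiotic P450 and erythroid genes had 0.745. Leaving out each library gave 0.329 to 0.976 for xenobiotic P450, 0.0874 to 0.990 for acute phase, 0.386 to 0.964 for erythroid and 0.217 to 0.929 for mitochondrial genes. The cause was not tested.

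A replicate block, using the numbers in the titles, gave 3717 genes and 29 lists, with adjusted p = 0.998 for erythroid genes and 0.0378 for circadian clock genes, which it added to the calls. Library deviations from their group means did not correlate best between equal numbers (-0.12, 0.04 and -0.04), so pairing was not established.

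Of the 55 genes named by the rule 45 passed in every alternative that gave a value, and 10 lost the call in at least 1 (Dmbt1, Serpina1e, Moxd1, Mup15, Mup16, Cox5a, Jchain, Alas2, Rps2 and Kdm5d). Of the 98 further examples 69 passed throughout and 29 lost the call in at least 1. No sign changed among either set. Among the genes named in the report, total counts ended the calls of Abhd5, Alas2, Bbc3, Cat, Cideb, Clock, Cox5a, Fabp1, G6pc, Gcgr, Hspa1b, Kdm5d, Pdk4 and Rps2 (adjusted p from 0.0638 to 0.848). Leaving out the 2 libraries ended those of Ctsc, Dmbt1, Fasn, Gcgr, Gzmb, Hspa1b, Jchain, Kdm5d, Moxd1, Ms4a1, Nkg7, Scd1 and Serpina1e (0.0580 to 0.248). Genes with few control counts are limited by depth, at a floor of 3 counts per library, or 0.199 to 0.255 CPM of total counts.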

Other observations

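The tests of depth, sex, hepatocyte share, near-identical copies and blood, the length-matched comparison of receptor genes, and the gene families and annotation terms were chosen only after the result was seen. All explanations below are hypotheses. Bootstrap SDs came from resampling the genes of a list, not the libraries. They leave out the spread between libraries and the correlation between genes.

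Model libraries had a count for more genes than control libraries, and 881 genes had counts in all 3 model and no control libraries, against 4 the other way. These 881 had a median of 11 counts over the model libraries, and 94 of them had 30 or more. Greater depth was not the whole cause: thinned to the shallowest total, the lowest model library had 16085 genes, above the highest control library with 14040, and thinned also by the ratio of TMM factors, for reads freed from abundant transcripts, it had 15694. Genome-wide background such as genomic DNA would raise receptor genes of smell like others, but the share of such silent genes gaining counts was 0.130 of that of other genes (4.19% against 32.2%), or 0.0991 at matched lengths. The regimen itself, with cells entering or changing in the liver, stays open and may be the cause.

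Male-biased liver genes were lower and female-biased genes higher in the model. A library from female mice alone, as after a sex swap, would lack Y-linked transcripts, but the lowest ratio of a Y-linked gene to the control mean was 0.583 (Kdm5d in model replicate 1). These ratios cannot decide on a pool with some female tissue, and the listed gene Xist was not among the genes measured. A lower share of hepatocytes would lower male-biased genes as it lowers hepatocyte identity genes, but the male-biased median lay further down by a log2 difference of -2.12 (bootstrap SD over genes 0.55). This argues against a lower share as the whole cause. Reads shared between copies would leave other members unmoved. Outside the Cyp2, Cyp3a, Cyp4a, Mup, Sult, Serpina1 and Ugt families, with no filter on low counts, the medians were 2.28 for female-biased (SD over genes 0.67) and -3.23 for male-biased genes (SD over genes 0.79). Members of other numbered families, such as Selenbp2, Gstp1, Hsd3b5 and Acot3, stayed in, so only the families left out were tested. Among the female-biased genes outside those families, Atp6v0d2 is also a listed macrophage marker and Acot3 a listed gene of fatty acid oxidation. The rise of this set is therefore not independent of theirs. An effect of the regimen on sex-biased expression may remain, untested.

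Immune cell markers rose while hepatocyte markers fell. A lower share of hepatocytes alone would raise markers of all other cells alike, but the macrophage median exceeded the endothelial one by 2.72 (bootstrap SD over genes 0.375). This argues against a lower share as the whole cause, though it may contribute. Blood left in the tissue would raise globins at least as much as neutrophil genes (median 2.47), but the highest globin value was 0.71 (Hbb-bs, SE 0.47). That neutrophil median came from the 7 of 12 listed genes that passed the count filter, which favours rises. More or altered macrophages under the regimen stay open as a candidate explanation.

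The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. For genes, 1 of 10 splits gave as many as the real one, with 4388 genes against a highest other value of 0 by edgeR, where 66 to 398 genes had an unadjusted p under 0.05. For lists, 1 of 10 splits gave as many, with 28 against a highest other value of 24 by camera with its preset correlation. Each other split mixed control and model libraries. Part of the real difference then stays between the groups, and the rest adds to the spread within them. Few gene calls in such splits were thus to be foreseen, and neither count tests chance.

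Gene families, several of which share members with the fixed lists and so are not independent of them, were compared with all tested genes by Fisher's exact test, with Bonferroni adjustment over 333 families in 2 directions. The test treats genes as independent, so its p-values are too small where members of a family move together. Guanylate-binding proteins were higher in 10 of 10 genes (median 2.19, adjusted p = 1.1e-04), the Ms4a family in 9 of 10 (3.29, 0.0041) and C-type lectins in 15 of 21, with 2 lower (2.29, 6.2e-04). Carboxylesterases were lower in 9 of 14, with 1 higher (-1.61, 0.0118), and A-clade serpins in 11 of 16, with 3 higher (-1.07, 4.8e-04). Toll-like receptors (8 of 10 higher, 0.0729), schlafens (6 of 6, 0.0559), annexins (8 of 11, 0.218) and keratins (6 of 7, 0.321) did not pass, nor did major urinary proteins (8 of 20 lower, 1.0) and acyl-CoA thioesterases (6 of 11 higher, 1.0).

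Of 6 annotation terms in the table, adjusted in the same way over 3286 terms, immune response was higher in 85 of 134 genes, with 9 lower (median 1.75, adjusted p = 7.89e-23). Peroxisome was lower in 38 of 120 genes, with 15 higher (0.0022), although Ehhadh, a peroxisomal gene of the report, was higher. Coagulation was lower in 23 of 60, with 13 higher (0.0118), and ribosome constituents in 50 of 156, with 1 higher (2.0e-05). The medians of these 3 terms were -0.31, -0.36 and -0.41 and became 0.18, 0.13 and 0.08 under total counts, so their direction depends on the scaling. Classical complement (13 of 26 lower, 5 higher, 0.0704) and lysosome (84 of 340 higher, 35 lower, 1.0) did not pass. For these terms, too, the test treats genes as independent, and correlation between members makes its p-values too small.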
